A study of Oryza sativa Japonica Group with 2 samples.

How the data were processed

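RNA from 7-day-old seedlings of 2 rice cultivars, Gimbozu EG4 (EG4) and Nipponbare, was compared on 2 Agilent rice oligonucleotide arrays with 2 colours each. Per the labels' protocols, RNA was purified with a Qiagen plant kit, 400 ng were labelled by linear amplification, and 1 µg of labelled cRNA of each dye was applied. On the array of replicate 1, EG4 was in Cy5 and Nipponbare in Cy3. On the array of replicate 2 the dyes were swapped. The labels name 2 extracts per cultivar as replicates, while the design text speaks of 4 biological replicates, and how these map to the 2 arrays is not given in the sources used here. The p-values therefore measure the spread between these 2 arrays, which may be technical. Both arrays lay on 1 slide and in 1 scan, so neither was a batch term.

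Per the file headers, the deposited intensity values were extracted with Agilent Feature Extraction 9.1.3.1, protocol GE2-v5_91_0806, from array design 015241. They are spot means and local background medians, not normalized. A further set of deposited intensity values is the software's processed signal, background-subtracted and dye-normalized by linear and LOWESS steps per the file headers. The deposited log10 ratio is Cy5 over Cy3 of those processed signals, per the file headers. Flags for signal well above background, saturation and outlier spots are other deposited values of 0 or 1, per the file headers. The authors' series table holds the log10 ratio with the sign of the second array turned, so that both columns run EG4 over Nipponbare. It matched the scanner values within 0.005, with column medians of 0 and -0.0117. No further scaling or centring was found in it.

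Each array held 45151 spots, of which 1417 were controls. The 42105 spots of named rice loci made up 41889 probes of 29689 loci. With limma 3.58.1 in R 4.3.3 (tables read with the package data.table, version 1.17.8), signals were corrected by normexp with an offset of 50, and log2 ratios were normalized by loess within each array, with control spots at weight 0. Outlier spots (177 and 140 among the gene spots) were left out, and 0 spots were saturated. Spots of 1 probe were averaged, and each gene took its probe of highest mean intensity. Genes were kept when well above background in EG4 on both arrays or in Nipponbare on both arrays, which left 22353 genes, 19454 of them well above background in all 4 channels. Every ratio was turned to EG4 over Nipponbare. Gene names are the descriptions in the array files, which can be old. The reference gene table does not carry these locus identifiers and was not used for names, and chromosome and gene order were read from the locus identifier, with no coordinates.

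The ratios were tested with lmFit and eBayes against 0, with Benjamini-Hochberg adjustment and a threshold of 0.05. A ratio on 1 array compares the extracts that share a replicate number, so the array is the block. With 1 residual degree of freedom per gene, limma estimated an infinite prior, so all genes shared an SD of 0.17 and a standard error of 0.12. The test is then in effect a fold threshold: the smallest difference called was 0.29 on the log2 scale, or 1.22-fold. A count of genes at least 2-fold apart in the same direction on both arrays, which has no test, was therefore made beside it. For genes well above background in 1 cultivar on both arrays and in the other on neither, only a bound is given. It sets the bright cultivar's mean, after loess and Aquantile, against the higher of the dim probe's own signal and the lowest signal of any probe well above background. Each cultivar's mean holds both dyes. The words "at least" refer to the mean of both arrays, and 1 array can lie below it. Where the dim probe's own signal was the higher, the bound equals the mean ratio.

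Before the data were examined, 24 gene lists were fixed as patterns on the descriptions or as locus identifiers. They are transposable elements, resistance proteins with NBS-LRR and related domains, receptor-like kinases, pathogenesis-related proteins, heat shock proteins and chaperones, cold, drought and ABA responses, light harvesting and photosystems, ribosomal proteins, histones, cytochrome P450, glutathione S-transferases, class III peroxidases, terpene and diterpenoid synthesis, seed storage, alpha-amylases, root markers, pollen and anther markers, cell wall, WRKY, NAC and AP2/ERF factors, F-box proteins, DNA methylation and small RNA, and flowering and clock loci. They were tested with camera at a preset correlation of 0.01, two-sided, and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry stood beside it. The estimated correlation and its test rest on 1 residual degree of freedom, so hardly any list could reach a small p. It cannot decide how far correlation between genes weakens a list's result. Adjacency of 2-fold genes in locus order was tested by 10000 permutations, one-sided.

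The rule for named genes was also fixed before. It takes the 8 largest called differences with an assigned function in each direction among genes well above background in all 4 channels, and the 2 largest of any description. It also takes the 3 largest bounds with an assigned function in each direction, up to 4 members of each list by smallest p, and every called flowering locus. Descriptions reading "no hit" or naming only a domain of unknown function were counted as having no function, and the former exclusion was added after values had been seen. From these, the text names a part.

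The fit was tested on simulated data: 22353 genes with residuals resampled from the real arrays with genes changed at 4 fold sizes, 50 per size. It recovered 45 of 50 genes changed 1.5-fold, 50 of 50 changed 2-fold and 50 of 50 changed 4-fold, but 8 of 50 at the smallest fold simulated. Of 209 calls, 56 were unchanged genes, and 38 genes were called where none was changed, so false calls exceeded the nominal rate in the simulation. Fewer genes were changed there than the 8076 called on the real arrays, so the share of false calls does not carry over. No unchanged gene was 2-fold apart on both simulated arrays (0 of them). Residuals were drawn separately for each array, so an error shared by both could not arise.

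Alternatives covered the background correction, the normalization, the filter, the probe rule, the offset, the series table, the pairing of channels, the direction of the ratios, a shift of the median of all genes, each array alone, thresholds and set tests. The number of arrays limits the precision. Median signal over background was 5.21 for Nipponbare and 17.0 for EG4 on the array of replicate 1, and 5.92 for EG4 and 12.1 for Nipponbare on that of replicate 2.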

Results

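Transcript levels of 22353 genes were compared between 7-day-old seedlings of 2 healthy rice cultivars grown in a greenhouse at 26 °C. EG4 is a strain known for active transposition of the small DNA transposon mPing, and Nipponbare is the cultivar of the rice reference genome. Each of 2 arrays held 1 extract of each cultivar, with dyes swapped between arrays. The share of probes well above background was 70.1% for Nipponbare in Cy3 and 80.1% for EG4 in Cy5 on the array of replicate 1. On the array of replicate 2 it was 78.2% for EG4 in Cy3 and 78.8% for Nipponbare in Cy5. Across genes, which are not independent replicates, the ratios of both arrays correlated with r = 0.941 after being turned the same way. Before turning, the log10 ratios of gene spots had r = -0.847.

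The comparison of EG4 with Nipponbare asks which genes differ in level between these cultivars. Among genes measured in both, the largest higher values in EG4 belonged to a 4,5-DOPA dioxygenase (Os01g0878900), with a log2 ratio of 5.94 ± 0.70 (SD, n = 2), and a lipid transfer protein (Os11g0115100), with 5.87 ± 0.12 (SD, n = 2). A fasciclin domain protein (Os01g0668100, 5.65 ± 0.14), a leucine-rich repeat protein (Os02g0616100, 5.32 ± 0.14) and the lipid transfer protein LTP 3 (Os12g0114800, 5.24 ± 0.48) followed. An isocitrate lyase family protein (Os12g0189300, 5.02 ± 0.27), a glucosyltransferase family protein (Os04g0206500, 5.01 ± 0.11) and a germin-like protein (Os08g0460000, 4.94 ± 0.10) completed the 8 with an assigned function. Each value is that of 1 probe per gene: over all measured probes Os02g0616100 ranged from 3.01 to 5.67 (21 probes) and Os08g0460000 from 3.86 to 4.99 (5 probes). Of any description, a hypothetical protein (Os03g0422200) had the highest ratio, 6.27 ± 0.00056. All errors given in this form are SDs of 2 arrays.

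The lowest ratio was that of a homolog of the Clp protease subunit clpA (Os12g0230100), at -8.47 ± 0.18. An oxo-phytodienoic acid reductase (Os06g0215900), of the enzyme family that includes a step of jasmonate synthesis, had -5.21 ± 0.15. The glycine-rich RNA-binding protein GRP1A (Os12g0632000) had -4.88 ± 0.74 and monosaccharide transporter 3 (Os07g0131600) had -4.83 ± 0.15. Both Os11g0229500 (-4.72 ± 0.49) and Os11g0605100 (-4.0 ± 0.05) are described as disease resistance proteins, and 3 probes of the former ranged from -4.98 to -3.65. An NADPH HC toxin reductase (Os07g0601000, -4.44 ± 0.10) and a leucine-rich repeat protein (Os01g0162300, -3.67 ± 0.0074) were also lower. A conserved hypothetical protein (Os04g0630400) had -6.59 ± 0.38. Each of these 18 genes passed the limma test in the same direction on both arrays.

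**Figure D1:**
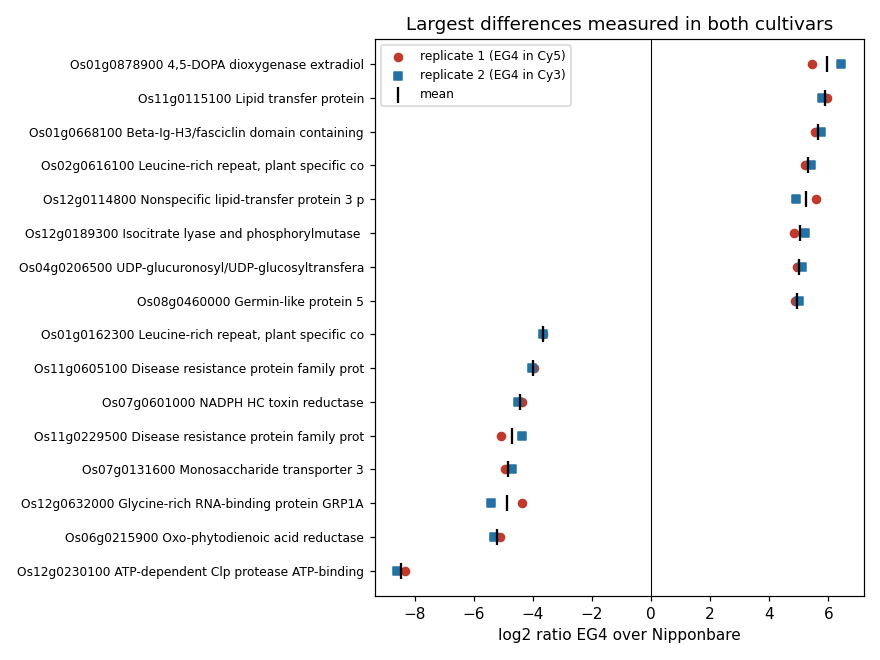
Log2 ratio of EG4 over Nipponbare for the 8 largest differences in each direction among genes with an assigned function measured in both cultivars. Circles and squares are the 2 arrays and bars their mean; means run from -8.47 to 5.94.

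By limma, 8076 of 22353 genes passed an adjusted p of 0.05, 4961 higher and 3115 lower in EG4, and 8045 of them had the same direction on both arrays. At least 2-fold on both arrays, 1266 genes were higher and 295 lower, with 0 in opposite directions. At 4-fold the counts were 381 and 108. The called split of 61.4% higher depended on the scaling. With the scanner software's processed signals it was 47.8% (3389 higher, 3708 lower), and with the series table's values 48.3% (3323 and 3559), where the median of all genes lay at -0.11 against 0.0083. With that shift removed, chosen after seeing the data, it was 61.6% (3950 and 2467) and 61.9% (3863 and 2382). It was 78.3% with median centring (987 and 273). With only genes well above background in all 4 channels it was 53.7% (3697 and 3189). The 2-fold genes higher in EG4 outnumbered those lower by 4.29 to 1, and by 3.25 to 5.22 over the other settings for the same fold, apart from ratios left unturned, which gave 0 of each.

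**Figure D2:**
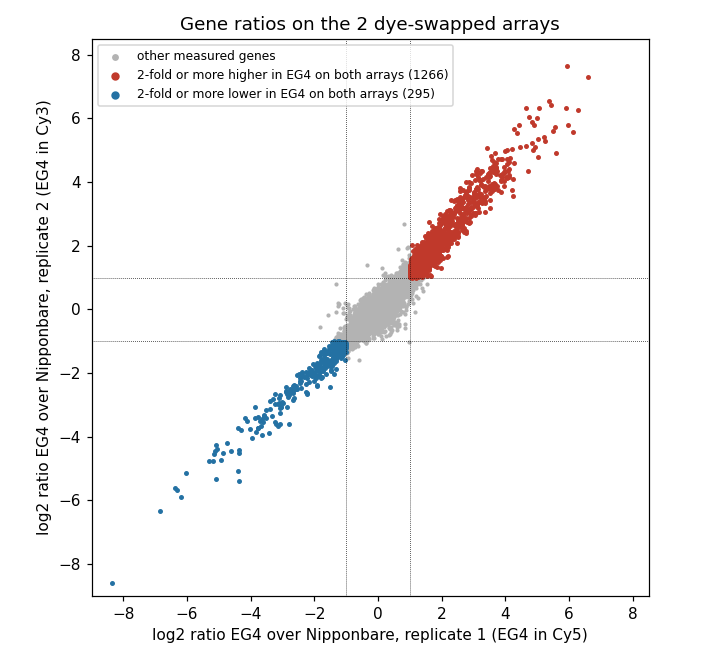
Log2 ratio of each gene on the array of replicate 1 (x) and replicate 2 (y), both as EG4 over Nipponbare. Coloured points are the 1266 genes higher and 295 lower by at least 2-fold on both arrays; dotted lines mark 2-fold.

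In 799 genes only EG4 was well above background, and in 118 only Nipponbare, on both arrays. A class B acid phosphatase (Os05g0190500) was at least 104-fold higher in EG4, a GDSL lipolytic enzyme (Os02g0816200) at least 49.1-fold and a ZmGR1a protein (Os02g0662100) at least 41.8-fold. A protein kinase (Os02g0615800) was at least 62.8-fold lower in EG4, a Brix domain protein (Os01g0148400) at least 53.5-fold and an En/Spm-like transposon protein (Os06g0271500) at least 23.0-fold. These bounds are of the mean of 2 arrays, and 1 array can lie below them. On the log2 scale Os05g0190500 had a bound of 6.70, and ratios to the dim signal of 5.93 (replicate 1) and 7.64 (replicate 2). As log2 ratios to the dim signal itself, which are not measured sizes, probes of Os05g0190500 ranged from 5.64 to 6.99. Those of Os06g0271500 ranged from -4.68 to -3.13. The bound reached 2-fold in 277 and 81 of these genes. Single arrays gave other counts: 3383 EG4 only and 240 Nipponbare only without replicate 2, 856 and 1063 without replicate 1. Grouped by dye in place of cultivar, 421 genes were well above background in Cy5 only and 6 in Cy3 only.

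The gene lists ask whether groups of related genes differ together. Cell wall genes were higher in EG4: of 125 measured, 85 were higher, 4 lower and 36 did not pass, and adjusted over the list alone 86 were higher and 5 lower. The alpha-expansins OsEXPA5 (Os02g0744200, 4.14 ± 0.24) and OsEXPA7 (Os03g0822000, 3.83 ± 0.54) and the beta-expansin EXPB4 (Os10g0556100, 3.96 ± 0.15), from families that loosen cell walls, were among them. The 6 probes of EXPB4 (Os10g0556100) ranged from 1.65 to 3.96. The list's median ratio was 0.60, with an adjusted camera p of 9.5e-20 and adjusted p = 0.646 with an estimated correlation. The latter was hardly able to pass for any list, so here and below it decides nothing. Of 72 class III peroxidases, 47 were higher, 4 lower and 21 did not pass, with 49 and 5 adjusted over the list alone. Examples are Os01g0378100 (3.47 ± 0.12) and peroxidase 27 (Os07g0104100, 3.43 ± 0.29), the latter well above background in Nipponbare on 1 array. Their median was 0.68, with an adjusted camera p of 1.06e-15 and adjusted p = 0.646 with an estimated correlation. Without a filter on dim probes the medians of both lists were 0.12 and 0.14.

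Of 43 histone genes, 22 were higher, 2 lower and 19 did not pass, with 23 and 2 adjusted over the list alone. Histone H4 genes Os04g0583600 (2.77 ± 0.03) and Os02g0684500 (2.35 ± 0.0093) and a histone H3 gene (Os06g0160100, 2.38 ± 0.64) led the list. Histone genes are near-identical copies, so probes may share signal between them. The median was 0.33, with an adjusted camera p of 0.000194 and adjusted p = 0.646 with an estimated correlation. Of 121 pathogenesis-related proteins, 63 were higher, 17 lower and 41 did not pass, with 65 and 17 adjusted over the list alone. Chitinases, which cleave chitin, included Os10g0543400 (4.16 ± 0.07) and Os04g0494100 (4.00 ± 0.05), and a Bet v I family protein (Os04g0465600) had 3.90 ± 0.48. The median was 0.31, with an adjusted camera p of 0.000103 and adjusted p = 0.646 with an estimated correlation. The list shares 27 genes with the AP2/ERF factors, which are transcription factors, and it was not tested without them.

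The seed storage list, fixed as a marker of residual seed tissue, had 24 of 38 genes higher, 3 lower and 11 not passing, with 25 and 4 adjusted over the list alone. Its leading members are proteins with a lipid transfer, seed storage and trypsin-alpha amylase inhibitor domain, among them Os04g0554800 (4.54 ± 0.68) and Os01g0814100 (4.21 ± 0.18), a domain also found in lipid transfer proteins outside seeds. In Nipponbare both were well above background on 1 array. The median was 0.55, with an adjusted camera p of 2.22e-15 and adjusted p = 0.646 with an estimated correlation. The list did not pass when cut to its members well above background in all 4 channels. Storage proteins and oleosins alone, chosen after seeing the data, had 4 of 10 higher and 3 lower, with a median of 0.04. The unadjusted camera p of this part was 0.58. Of 11 pollen and anther markers, 5 were higher, 1 lower and 5 did not pass, with the same counts adjusted over the list alone. The members that differed most are allergen and extensin domain proteins such as Os10g0371000 (2.30 ± 0.13) and an expansin domain protein (Os06g0725300, 1.65 ± 0.12), and 3 members are also on the cell wall list. The adjusted camera p was 0.0487, and adjusted p = 0.646 with an estimated correlation. Without allergen, expansin and extensin members, chosen after seeing the data, the median was 0.0029. The list also did not pass without background subtraction, with processed signals, the series table, no filter or the filter on all 4 channels. The same held for offset 0, no replicate block and the list cut to members well above background in all 4 channels. Of these 6 lists only the pathogenesis-related proteins passed fry (adjusted p = 0.0412).

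**Figure D3:**
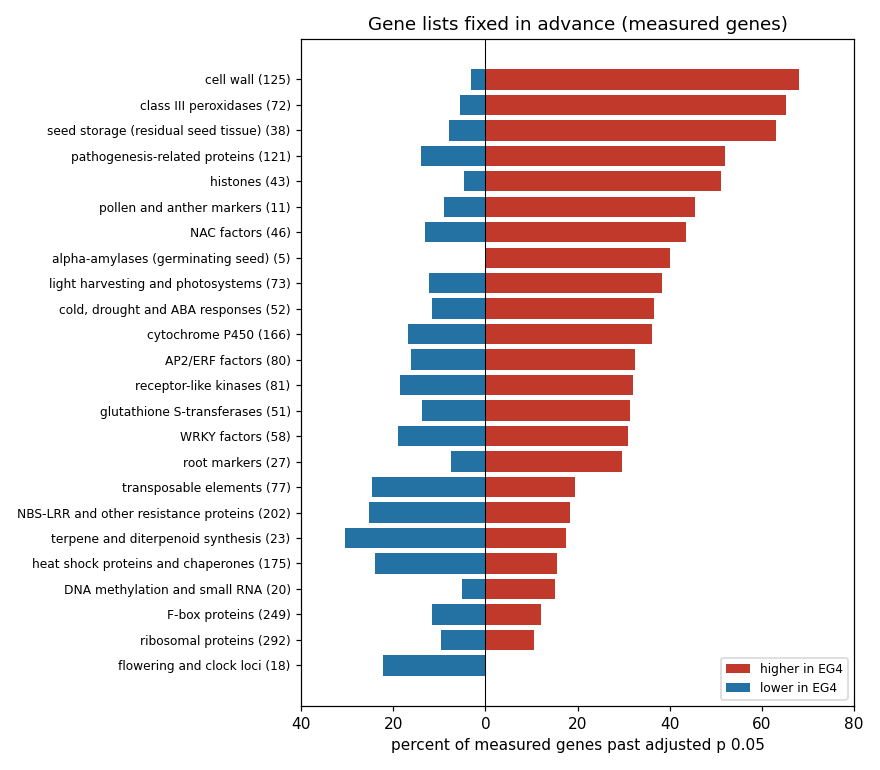
Percent of the measured genes of each list that passed the limma test, with genes higher in EG4 to the right and lower to the left; the number measured stands in brackets. Cell wall (85 of 125) and class III peroxidases (47 of 72) lie at the top and flowering loci (0 higher, 4 of 18 lower) at the bottom.

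The other 18 lists did not pass the camera test. Among light harvesting and photosystem genes 28 of 73 were higher and 9 lower, and many of the higher are plastocyanin-like proteins such as Os06g0218600 (2.24 ± 0.10). A chlorophyll a-b binding protein (Os01g0720500), part of the light-harvesting antenna, had 2.25 ± 0.05. Adjusted over the list alone the counts were again 28 and 9. Root markers had 8 of 27 higher and 2 lower, among them nicotianamine synthase 9 (Os07g0689600, 1.53 ± 0.23), with the same counts adjusted over the list alone. Alpha-amylases, active in the germinating seed, had 2 of 5 higher and 0 lower, again the same adjusted over the list alone. One of these, Os04g0526600 (0.69 ± 0.06), is an inhibitor of alpha-amylase, well above background in Nipponbare on 1 array, and did not pass by limma without the replicate block or with median centring.

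Among 202 resistance proteins 37 were higher and 51 lower (40 and 52 adjusted over the list alone). Os11g0645400 had 4.90 ± 0.17, while Os11g0606400, well above background in EG4 on 1 array, had -4.53 ± 0.11. Of 58 WRKY factors 18 were higher and 11 lower, with the same counts adjusted over the list alone. WRKY41 (Os11g0685600) and WRKY61 (Os11g0685700) had the lowest ratios of the list. They were not well above background in EG4, where they were at least 10.5-fold and 10.2-fold lower. The probe names of both cite the same transcript record, so their values may not be independent. Transposable elements had 15 of 77 higher and 19 lower (16 and 20 adjusted over the list alone). A MuDR transposase domain protein (Os07g0102900) was at least 5.72-fold lower in EG4. The En/Spm-like protein Os02g0230300, also described as protodermal factor 1, was at least 17.0-fold higher and not well above background in Nipponbare.

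Of 51 glutathione S-transferases 16 were higher and 7 lower (16 and 9 adjusted over the list alone), including GSTF14 (Os03g0134900, 3.48 ± 0.07) and GSTF15 (Os03g0135100, 3.63 ± 0.62), the latter well above background in Nipponbare on 1 array. Second probes of Os03g0134900 and Os03g0135100 gave 1.61 and 2.21. Cytochrome P450 genes had 60 of 166 higher and 28 lower (61 and 30 adjusted over the list alone). Terpene and diterpenoid synthesis had 4 of 23 higher and 7 lower, with the same counts adjusted over the list alone. Of 2 loci described as ent-kaurene oxidase, an enzyme of gibberellin synthesis, Os06g0569900 was at least 7.61-fold higher in EG4 and not well above background in Nipponbare, and Os06g0570100 had -1.21 ± 0.19. A second probe of Os06g0570100 gave 0.04, and the gene did not pass with median centring. Receptor-like kinases had 26 of 81 higher and 15 lower (27 and 16 adjusted over the list alone), AP2/ERF factors 26 of 80 and 13 (27 and 13), and NAC factors 20 of 46 and 6 (20 and 8). Cold, drought and ABA responses had 19 of 52 higher and 6 lower (19 and 7 adjusted over the list alone), and heat shock proteins and chaperones 27 of 175 and 42 (27 and 46).

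Ribosomal proteins had 31 of 292 higher and 28 lower (24 and 21 adjusted over the list alone), and F-box proteins 30 of 249 and 29 (30 and 24). DNA methylation and small RNA genes had 3 of 20 higher and 1 lower, with the same counts adjusted over the list alone. The DNA methyltransferase MET1 (Os07g0182900) had 0.45 ± 0.05 and argonaute 4 (Os07g0471300) 0.35 ± 0.01, and neither passed with the scanner software's processed signals, the series table's values or median centring (0.33 and 0.30). Camera compares a list with the other genes, and median, mean and test differed in sign in 6 lists. Receptor-like kinases had a median of 0.05 and a mean of 0.10 with a test direction of down, and WRKY factors 0.01 and -0.10 with down. Resistance proteins had -0.04 and 0.0012 with down, ribosomal proteins -0.0085 and 0.0025 with down, and DNA methylation genes -0.06 and 0.0031 with down. Glutathione S-transferases had -0.00022 and 0.26 with up.

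Among flowering and clock loci, 18 of 22 were measured: 0 were higher, 4 were lower and 14 did not pass, with the same counts adjusted over the list alone. HAP3 (Os08g0174500) had -1.04 ± 0.03, and Hd1 (Os06g0275000), a regulator of flowering by day length, had -0.44 ± 0.02 with an adjusted limma p of 0.00131. A MADS-box factor (Os03g0752800) had -0.38 ± 0.13 and a response regulator (Os02g0618200) -0.33 ± 0.0044, with adjusted limma p of 0.00628 and 0.0228. None of these 4 passed with median centring, where their ratios were -1.10, -0.45, -0.49 and -0.33, and Os02g0618200 did not pass with a normexp offset of 0 either (-0.34). The list did not pass the camera test (adjusted p = 0.22).

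The last planned comparison asks whether genes that differ lie next to each other. Among measured genes in locus order, 171 adjacent pairs were 2-fold apart in the same direction on both arrays, against a mean of 75.4 and a maximum of 109 in 10000 random placements. The one-sided permutation p was 1e-04, the smallest these draws can give. There were 20 runs of 3 or more such genes, 17 higher and 3 lower. The following runs were chosen after their values were seen. GSTF14, GSTF15 and GST 9 (Os03g0135200, 2.44, Nipponbare well above background on 1 array) lie together on chromosome 3. On chromosome 11, WRKY41, WRKY61 and the En/Spm-like protein Os11g0686000 (-2.74, EG4 well above background on 1 array) belong to a run of 5 lower genes. On chromosome 2, 6 neighbouring loci from Os02g0559800 to Os02g0561800 had ratios between -1.37 and -1.32, of which 5 have no described function. Second probes of these 5 gave -1.03 to -0.95, some of them under 2-fold. Values so alike may not be independent, which was not tested. On chromosome 10, a run of 6 genes described by the same domain of unknown function included Os10g0150400, with 6.11 and well above background in Nipponbare on 1 array.

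The share of measured genes at least 2-fold lower in EG4 on both arrays was 3.13% on chromosome 11 (38 of 1214) and 0.49% on chromosome 5 (9 of 1836). For genes higher it lay between 4.35% on chromosome 9 and 6.59% on chromosome 4. A permutation test of evenness, chosen after seeing the data, gave 1e-04, the smallest possible, for lower genes and 0.126 for higher genes. It placed genes singly, while lower genes also lay in runs, so it cannot tell uneven chromosomes from local clusters.

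**Figure D4:**
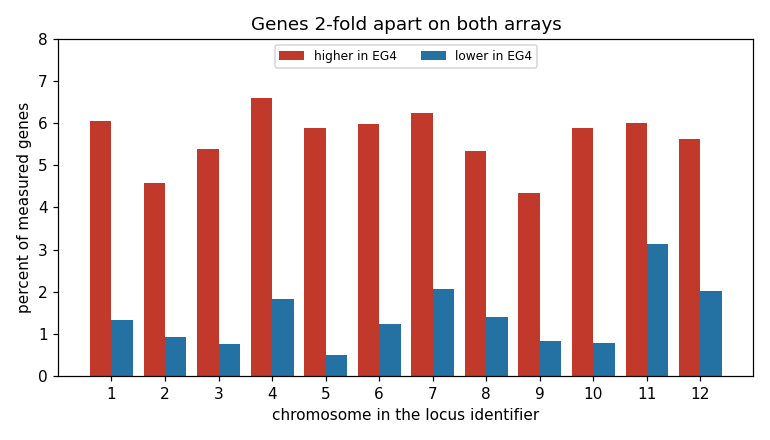
Percent of measured genes on each of the 12 chromosomes that were at least 2-fold higher or lower in EG4 on both arrays, with chromosomes read from the locus identifier. Lower genes range from 0.49% on chromosome 5 to 3.13% on chromosome 11.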

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

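Probes for microRNA loci belong to none of the comparisons, and this count was chosen after seeing the data. Of 510 such probes, 68 were well above background in a cultivar on both arrays. All 68 were so in EG4, and only 37 of them in Nipponbare too. Against this stood 0 of 11 control probes for genes of other plants, 0 of 12 named random and 0 of 12 named art. Of 24 control probes named genome, whose target is not given in the sources used here, 2 were well above background in both cultivars on both arrays, a share of 8.33% against 13.3% for the microRNA probes (two-sided Fisher's exact p = 0.756). The other control classes gave Fisher's exact p of 0.374 and 0.381. At 0 of 11 or 12 probes a low p was not possible in classes this small, so these tests cannot decide. The classes were not tested together. The count is therefore not shown to lie above that of the genome class, and stays undecided for the others. None of the 68 was 2-fold apart on both arrays (0 probes), a count that was looked at first.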

How the results depend on the processing

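The 4 alternatives that split list members and the 2 that moved the median of all genes were chosen after seeing the data, and the others were fixed before. The number called stayed within 1.5 times of 8076 (6245 to 9353), except with median centring, all probes as separate features and ratios left unturned. Median centring gave 1260 (987 higher, 273 lower), and all probes gave 12192, of which 7640 were higher. Ratios left unturned gave 0 called (0 higher and 0 lower by limma), with 3 genes at an unadjusted p under 0.05. Unturned ratios cancel a cultivar difference in the mean and add it to the residual spread. Their 0 calls were therefore nearly fixed in advance and say nothing about dye bias. Otherwise the cause was not tested, except that all probes give more features. Aquantile changes intensities, not ratios, so its 8075 calls say nothing about stability.

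Genes 2-fold on both arrays numbered 2637 with the scanner software's processed signals (2016 higher, 621 lower, 6 opposite), 2633 with the series table (2014, 619 and 6) and 2384 with all probes (2001 higher). They numbered 948 with genes well above background in all 4 channels (743 higher), where fewer genes enter. Opposite directions numbered 54 with median centring, 1 with offset 0 and 1561 with ratios unturned, which left 0 in the same direction (0 higher, 0 lower). At 4-fold 489 genes passed (381 higher, 108 lower) and at 1.5-fold 3012 (2329 higher, 683 lower, 4 opposite). Each array alone gave 1739 to 1900 genes. For genes measured in 1 cultivar only, each array alone gave 1919 to 3623 in all, 856 to 3383 in EG4 only and 240 to 1063 in Nipponbare only. Grouped by dye the counts were 427, 421 and 6.

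Of 24 lists, 6 passed. With all probes 12 did, with ratios unturned 1, and with an estimated correlation 0, where 0 lists had an unadjusted p under 0.05. That correlation and its test rest on 1 residual degree of freedom, so hardly any list could pass and the count of 0 decides nothing. Fry kept only the pathogenesis-related proteins of the 6 (adjusted p = 0.0412) and added transposable elements, WRKY and AP2/ERF factors. The pollen and anther list also lost its call without background subtraction, with processed signals, the series table, no filter or the filter on all 4 channels. It lost it too with offset 0, no replicate block and the list cut to members well above background in all 4 channels. The seed storage list also lost its call when cut in that way.

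The test direction of receptor-like kinases turned without background subtraction (median 0.058), with processed signals (-0.057), no filter (0.016), all probes (0.048), the series table (-0.057), offset 0 (0.059), fry (0.048) and no replicate block (0.048). With fry it also turned for resistance proteins (-0.043), ribosomal proteins (-0.0085) and DNA methylation genes (-0.062). Without members measured in 1 cultivar only it turned for cytochrome P450 (0.031), glutathione S-transferases (-0.026) and NAC factors (0.126). It turned for light harvesting without plastocyanin-like proteins (-0.033) and for pollen markers without allergen, expansin and extensin members (0.0029). The cause of these turns was not tested.

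Adjacent pairs numbered 405 with processed signals and 405 with the series table, 264 with offset 0, 112 with median centring, 68 with the filter on all 4 channels and 383 within the next 3 genes, each at a permutation p of 1e-04. With ratios unturned there were 0, since no gene was then left to place, so the permutation p of 1 was fixed. Without the replicate block, which treats the channels as unpaired, 8267 genes were called and 6 lists passed, and the block changed no count by over 1.5 times, but without it 2 named genes (Os04g0526600 and Os06g0237900) lost their call. No named gene turned, but 21 lost their call with median centring, among them all 4 flowering loci, MET1, argonaute 4, Os04g0526600 and Os06g0570100. With the series values, 3 lost it (MET1 Os07g0182900, argonaute 4 Os07g0471300 and Os06g0237900), with processed signals 2 (MET1 and argonaute 4) and with offset 0, 1 (Os02g0618200), while Os02g0765300 gained a call under each of these.

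Not run were the count called on a single array, which leaves no residual degree of freedom, and adjacency with all probes, where probes of 1 gene would count as neighbours. Counts of genes measured in 1 cultivar only rest on detection flags, which normalization does not change, and their bounds were not recomputed. Lists on a single array have no test. With each array alone the medians of the 6 lists that passed were 0.57 to 0.67 for cell wall, 0.73 to 0.75 for class III peroxidases, 0.35 to 0.37 for histones, 0.27 to 0.31 for pathogenesis-related proteins, 0.52 to 0.64 for seed storage and 0.11 to 0.20 for pollen and anther markers. Among the other lists, the median turned sign between arrays for ribosomal proteins (0.05 without replicate 1, -0.07 without replicate 2). It also turned for F-box proteins (-0.08 and 0.008) and glutathione S-transferases (-0.0075 and 0.014). For DNA methylation genes it was -0.09 and -0.01. Cy3 had the lower signal over background on both arrays (5.21 and 5.92 against 17.0 and 12.1), which limits detection.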

Other observations

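Tests chosen only after the result was seen were those of the epidermis and cuticle list, root share, normalization, missing genes, chromosomes and neighbours that do not look alike. The members of the root share test were also changed after a first version on the whole light harvesting list (median 0.08) had argued against it. That median was 0.0094 without replicate 1 and 0.24 without replicate 2.

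For 102 genes of the epidermis and cuticle matched by description, the median was 0.65. The unadjusted camera p was 5.87e-39 at the preset correlation and 0.114 with an estimated correlation, which rests on 1 residual degree of freedom and cannot decide. Of these genes, 70 were higher in EG4, 4 lower and 28 did not pass. GDSL lipolytic enzymes Os06g0148200 (5.35 ± 0.62, SD, n = 2) and Os04g0507700 (4.63 ± 0.60), the fatty acid condensing enzyme CUT1 (Os01g0529800, 4.45 ± 0.42) and a CER1-like protein (Os02g0814200, 4.30 ± 0.60) were among them, each well above background in Nipponbare on 1 array. The list was written after lipid transfer and GDSL genes had been seen among the largest differences, so it is not independent evidence. The 4 probes of Os06g0148200 ranged from 2.48 to 5.35. For 184 cell division and replication genes, the unadjusted camera p was 0.00351 at the preset correlation and 0.128 with an estimated correlation. Of these, 70 were higher and 16 lower. Among the higher were a beta-tubulin (Os05g0413200, 2.61 ± 0.21) and the B-like cyclin CycOs2 (Os06g0726800), at least 4.23-fold higher and not well above background in Nipponbare. The pattern for that list also took in CUT1, which is not a cell division gene.

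More genes were 2-fold higher than 2-fold lower in EG4. The choice of normalization does not account for this, since the lowest ratio over 3 other normalizations was 3.25, but the excess among all called genes stays open, since their share higher was 47.8% with processed signals, 61.6% once their shift of all genes was removed, 60.8% without background subtraction and 78.3% with median centring. A larger share of dividing tissue in the EG4 seedlings may contribute: cell division genes had a median of 0.128, above the highest of 10000 random lists (0.127), yet between the bounds of 0.05 and 0.2 set before the test, so it stays open. A larger share of root also stays open. Photosystem members without plastocyanin-like proteins had a median of -0.033, with a 95% bootstrap interval of -0.14 to 0.08 over 46 genes. Genes on the same 2 arrays are not replicates, so the interval does not measure the spread between seedlings. Root markers had a median of 0.18, with 8 of 27 higher and 2 lower, but the list did not pass the camera test (adjusted p = 0.49). A difference between the cultivars themselves was not tested apart from these explanations, and the 2 arrays cannot separate it from how the seedlings were grown or sampled.

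Genes at least 4-fold lower in EG4 by their mean ratio might reflect sequence differences under probes, since the locus identifiers of the probes are those of the Nipponbare genome. In the 30 genes with a second measured probe, a difference under a single probe is argued against as the main cause. In 3.33% of them the second probe lay apart (exact 95% interval to 17.2%), and for genes 4-fold higher in 0.571% of 175. Whether both probes cover different sequence was not tested. For the rest of the lower genes, among them Os12g0230100 with 1 measured probe, this cannot be judged. The median GC content of the probes was 38.3%, inside the 35% to 45% that hold the middle of all genes. Of 118 such genes, 50% were well above background in EG4 on both arrays, which argues against absence of the gene for all of them, unless related sequences gave the signal, which was not tested. For the 51 genes well above background in EG4 on neither array, a missing gene and a silent one cannot be told apart, because both leave only a bound.

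Differing genes lay next to each other more often than in random placements, and whether tandem copies, or copies that share probe signal, account for this stays open. In 127 adjacent pairs the descriptions differed, against a mean of 69.7 and a maximum of 104 in 10000 placements, which met the bound set before the test, but that bound was too weak to exclude copies: 27 of these still shared a description word, a transcript record or a stretch of probe sequence, and another 55 held a gene of no assigned function. The other 45 pairs stood against a mean of 27.2 and a maximum of 47 (one-sided permutation p = 0.0006), so they did not exceed every placement, and some of them still join related families. Lower genes were also uneven over the 12 chromosomes, with a chi-square of 70.0 against a maximum of 47.9 in random placements. Those placements moved genes singly, so runs of neighbouring lower genes alone could raise the chi-square. The test therefore cannot tell unevenness between whole chromosomes from local clusters. A candidate explanation for either is that some chromosome segments differ more between the cultivars than others. A test of it would need sequence and transposon insertions of EG4, not analysed here.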
